A study of Mus musculus with 5 samples.

How the data were processed

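The deposited files held gene counts made by the authors, 1 file per library with 55291 gene symbols each. Per the labels' protocols, RNA was taken with an RNeasy mini plus kit and 1.3 ug of total RNA went into libraries made with a SMARTer mRNA-Seq kit. Per the submitters' processing notes, reads were trimmed with Trimmomatic and aligned to mm10 with STAR. Their versions, and the read counter, gene annotation and strand setting behind the counts, are not given in the sources used here. The protocol names no molecular identifiers, so the SD, SE, floors and intervals given here treat amplified reads as counts and cover counting error and spread between these libraries only.

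The counts were analysed as deposited with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr, which left 17062. Libraries were scaled by TMM, and CPM values use the TMM-adjusted library sizes. The genotypes were compared by edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its absolute value divided by the square root of F. The common biological coefficient of variation was 0.507. A level of 3 counts was taken as the floor, and 16704 tested symbols matched GENCODE M21 (GRCm38), from which positions were taken.

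Gene lists, tests, thresholds and alternatives were fixed before the data were examined, apart from 2 alternatives, the tissue lists and the later tests that are named as such. Of 29 lists tested by limma's camera with its preset correlation of 0.01, on log2 CPM with a prior count of 2, 19 were called, 14 higher and 5 lower. With an estimated correlation camera called 0, with 5 at an unadjusted p under 0.05, and fry called 10. Counts adjusted over the list alone use the Benjamini-Hochberg method within the list. Named genes were Tet2, the 12 largest rises and the 12 largest falls among called genes whose libraries did not overlap between genotypes, with a mean of 10 CPM or more in the higher genotype and no predicted, clone or pseudogene symbol, up to 4 called members of each list with the smallest p (up to 2 with the smallest unadjusted p where none passed), and the sex-linked genes, 118 in all. The other genes named, Cd40, Cd74, Cd80, Cd86, Cebpa, Ciita, Erap1, Gbp2, Gbp3, Gbp4, Gbp5, Gbp6, Gbp7, Gbp8, Gbp9, Hbb-bs, Ighm, Igll1, Il1b, Il6, Irf8, Isg15, Ly6c2, Mpo, Nfkbiz, Ngp, Nlrc5, Oas3, Spi1, Spic, Tff1 and Tnf, were chosen after their values were seen.

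Simulated counts with known changes in 16300 genes, made with the spread of these data, were put through the same test. It called 4 of 50 genes changed 2-fold, 32 of 50 changed 4-fold, 43 of 50 changed 8-fold and 47 of 50 changed 16-fold, all with the right sign, and made 7 false calls. A raised list was called by camera with its preset correlation (adjusted p = 3.25e-30), and 0 of 20 unchanged lists were. The simulated genes were drawn independently, so this does not test false calls of lists whose genes move together. Both genotypes were given the same spread, and as many genes were raised as lowered. The false calls therefore do not cover a wider spread between the mutant libraries, or a shift of many genes in one direction. The estimated correlation in the data was 0.694 for S phase and 0.977 for G2 and mitosis.

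Replicate numbers 2 and 3 occur in both genotypes, and the test was planned without the number. Correlations between libraries of one number after removal of the genotype means were -0.03 and -0.02. Across numbers they were 0.03 for wild-type replicate 2 with Tet2-mutant replicate 3, and 0.02 for wild-type replicate 3 with Tet2-mutant replicate 2. With 2 mutant libraries these values mirror each other by construction, so they say little about a pairing. The libraries with number 3 were both high in Xist and low in Y-linked transcripts, and those with number 2 both held Y-linked transcripts. Alternatives were other scaling, filters, tests and list tests, the replicate block, each library left out, and 2 chosen after the data were seen, namely the Xist class as a covariate and Tet2-mutant replicate 2 after subtraction of a wild-type share. Tissue lists were written after the pancreatic genes had been seen. A gene counted as higher where each mutant library was at least 4-fold above every wild-type library, with wild-type values raised to at least 0.0358 CPM, the lowest wild-type floor. The lists cover pancreatic acinar cells (21 of 25 genes with 10 or more counts higher), pancreatic islet (0 of 1), liver (0 of 1), skeletal muscle (0 of 8), intestine and stomach (0 of 5), brain (0 of 6) and spleen stroma and marginal zone (2 of 7, Cxcl13 and Ccl19). A test of the share of B cells against the class II rise is not reported here. Exons, splice forms and the site of the Tet2 mutation were not analysed here.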

Results

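RNA was sequenced from mouse bone marrow cells that the labels call monocytes, in 3 wild-type samples (replicates 1, 2 and 3) and 2 Tet2-mutant samples (replicates 2 and 3). How the cells were isolated, and what the letters HR in the titles of the mutant samples mean, are not given in the sources used here. Tet2 is an enzyme that oxidises methylcytosine in DNA and is often mutated in myeloid disease. The gene counts summed to 63910147, 72414875 and 53789308 in wild-type replicates 1, 2 and 3, and to 17459808 and 60508381 in Tet2-mutant replicates 2 and 3. At least 1 count was seen for 24532, 25612 and 26207 genes in the wild-type libraries and for 18047 and 17944 in the mutant libraries. After every library was thinned to the lowest total, 21192, 21525 and 22015 genes were detected in the wild-type libraries and 18047 and 15877 in the mutant libraries. Ngp, a neutrophil granule gene, was the most abundant transcript in all 3 wild-type libraries, with 2.54%, 2.18% and 1.84% of counts. Cd74, the invariant chain of MHC class II, led in Tet2-mutant replicates 2 and 3 with 2.99% and 2.83%. Transcripts of other cells were abundant too, with the globin gene Hbb-bs at 2756 to 8412 CPM and the immunoglobulin gene Ighm at 1018 to 4567 CPM in the wild type. Pearson correlations of log2 CPM (counts scaled to library size) across genes, which are not independent replicates, were 0.975 to 0.984 between wild-type libraries and 0.885 between the mutant libraries. With the wild-type libraries they were 0.904 to 0.910 for Tet2-mutant replicate 2 and 0.838 to 0.845 for replicate 3. By this measure Tet2-mutant replicate 2 lay closer to each wild-type library than to the other mutant library. A chi-square per degree of freedom on the raw counts gave the opposite order. It was 330 for Tet2-mutant replicate 2 with replicate 3, and 605, 568 and 561 with wild-type replicates 1, 2 and 3. Which library it resembled most thus depended on the measure. The labels do not say that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

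Tet2 itself (chromosome 3, 133463679 to 133545139 in GRCm38) stood at 11.9, 9.77 and 10.6 CPM in wild-type replicates 1, 2 and 3 and at 5.31 and 15.6 CPM in Tet2-mutant replicates 2 and 3. The genotype means were 10.8 ± 1.07 CPM (SD, n = 3) and 10.4 ± 7.25 CPM (SD, n = 2), and the log2 fold change of mutant over wild type was -0.04 ± 0.58 (SE; adjusted p = 0.966). The estimate was -1.02 (adjusted p = 0.0368) without Tet2-mutant replicate 3 and 0.53 (adjusted p = 0.113) without Tet2-mutant replicate 2. A mutation need not lower its own transcript, so this level does not check the genotype labels.

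The libraries of the Tet2-mutant samples held far more transcripts of antigen presentation than those of the wild type. All 16 measured genes of MHC class II presentation rose, with a median log2 fold change of 4.01, and H2-Ab1 went from 515 ± 120.0 CPM (SD, n = 3) to 20911 ± 6161 CPM (SD, n = 2). Of the lists of interferon-gamma response, macrophage, dendritic cell and T and NK cell genes, 17 of 24, 14 of 19, 8 of 14 and 12 of 24 members rose, while a few DNA replication genes and the neutrophil genes Padi4 and Mrgpra2b fell. Transcripts of pancreatic digestive enzymes, nearly absent in the wild type, were plain in both mutant libraries, with Cel at 93.2 and 202 CPM. Over the whole transcriptome, 2556 of 17062 tested genes changed between the genotypes (edgeR's quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05), with 1801 higher and 755 lower in the mutant, or 70.5% higher. For 2554 of them the libraries of the genotypes did not overlap, which is no separate support because the same libraries gave the calls.

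That count moved with single libraries. It was 622, 888 and 856 without wild-type replicates 1, 2 and 3, of which only 6, 18 and 14 were lower in the mutant. It was 10862, with 5958 lower, without Tet2-mutant replicate 2 and 7081, with 3300 lower, without Tet2-mutant replicate 3, where 1 mutant library was left and was assumed to vary like the wild type. Upper-quartile scaling moved the median log2 fold change of all genes by -0.27 and gave 1419 higher and 1837 lower genes, so that 43.6% were higher, and changes of that size are not separable from the scaling.

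**Figure D1:**
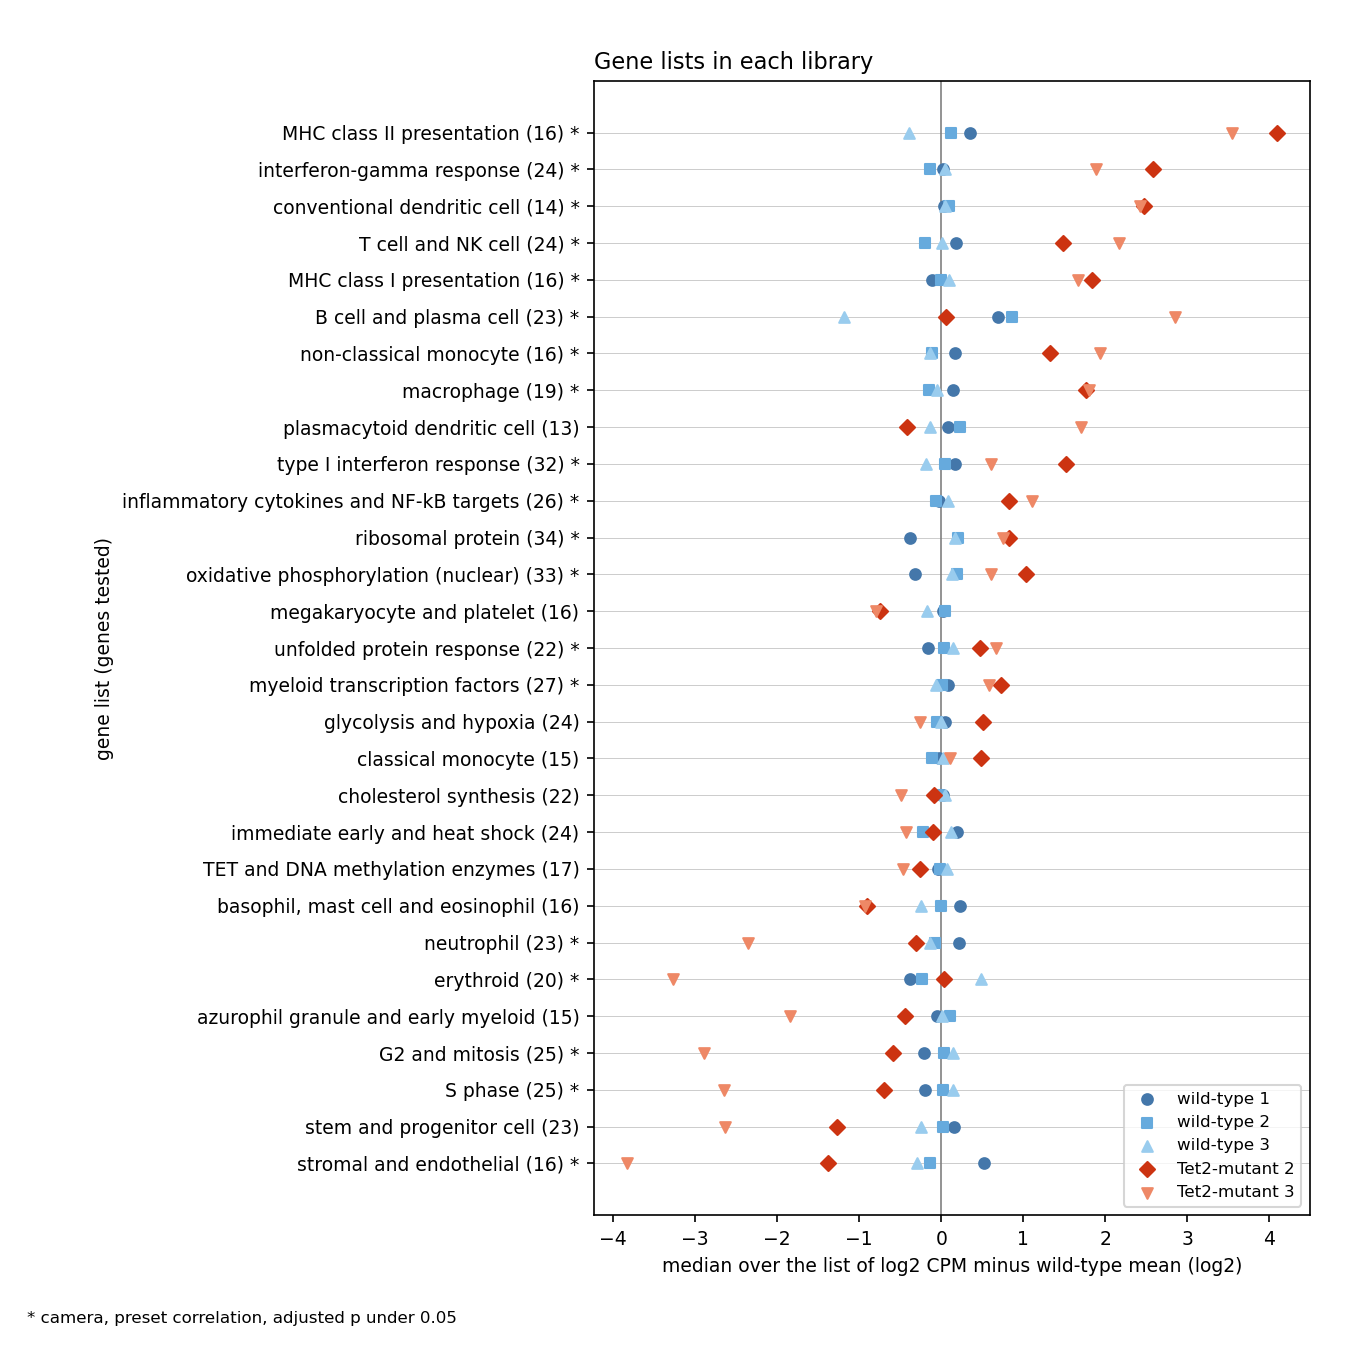
Median over each gene list of log2 CPM minus the wild-type mean (x axis, log2) for the lists fixed before the data were examined (y axis, number of genes tested in brackets, in the order of their median fitted log2 fold change), with 1 symbol per library. MHC class II genes lie at 4.09 and 3.54 in Tet2-mutant replicates 2 and 3, and the erythroid list lies at 0.03 in replicate 2 and at -3.27 in replicate 3.

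Antigen presentation through MHC class II showed the largest list median. H2-Aa, H2-Eb1 and H2-Ab1, which encode chains of the class II molecules that show peptides to CD4 T cells, lie together on chromosome 17 (34257689 to 34316674 from the start of H2-Ab1 to the end of H2-Eb1). H2-Aa rose from 195 ± 38.1 to 9283 ± 1460.1 CPM (SD, n = 3 and 2; log2 fold change 5.57 ± 0.33 SE, adjusted p = 0.000728), and H2-Eb1 from 138 ± 29.7 to 5409 ± 1536 CPM (log2 fold change 5.29 ± 0.35, adjusted p = 0.000848). Cd83, which stabilises class II molecules at the surface of dendritic cells, rose by 4.28 ± 0.31 on the log2 scale (adjusted p = 0.000848). The transcription factor Ciita, the master regulator of class II genes, and the costimulatory genes Cd40, Cd80 and Cd86 were among the 16 of 16 that rose, and all 16 also passed when adjusted over the list alone. The list was called by camera with its preset correlation (adjusted p = 8.06e-14), with an adjusted p = 0.28 with an estimated correlation. Members of the H2 family resemble each other, so reads may have been divided among them in the counting and single H2 values are uncertain. B cells, macrophages and dendritic cells all carry class II, and the macrophage and dendritic cell lists were also higher, with medians of 1.70 and 2.13. The B cell list median per library was 0.06 in Tet2-mutant replicate 2 and 2.85 in replicate 3, against 0.69, 0.86 and -1.19 in wild-type replicates 1, 2 and 3.

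Class I presentation moved in the same direction with smaller steps. Of its 16 measured genes 14 rose, over all genes and adjusted over the list alone while Erap1 and Nlrc5 did not pass. The list median was 1.77 (camera adjusted p = 6.88e-09, and adjusted p = 0.28 with an estimated correlation). B2m, the light chain of class I molecules, rose from 734 ± 91.3 to 5034 ± 469.8 CPM (SD, n = 3 and 2; log2 fold change 2.78 ± 0.26, adjusted p = 0.00181). The immunoproteasome subunits Psmb8 and Psmb10 rose by 2.85 ± 0.25 (adjusted p = 0.00156) and 2.47 ± 0.25 (adjusted p = 0.00212) on the log2 scale.

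**Figure D2:**
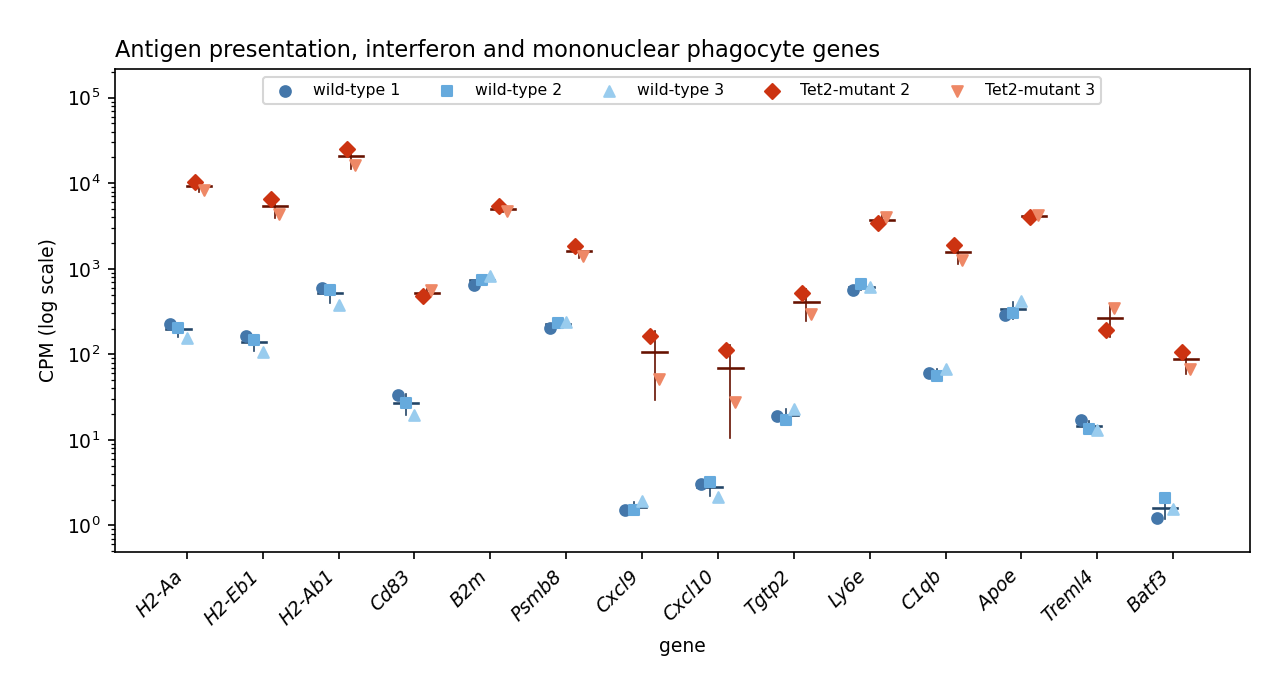
CPM (log axis) of 14 genes of antigen presentation, interferon response and mononuclear phagocytes in each library, with horizontal lines at the genotype means and vertical lines of 1 SD (n = 3 wild type, n = 2 Tet2 mutant). H2-Ab1 stands at 25268 and 16555 CPM in the mutant libraries and at 377 to 598 CPM in the wild type.

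Interferon-gamma response genes rose more often than not, 17 of 24 over all genes and 19 of 24 adjusted over the list alone, and none fell. The list median was 2.37 (camera adjusted p = 7.15e-11, and adjusted p = 0.28 with an estimated correlation). Cxcl9, a chemokine induced by interferon-gamma (chromosome 5, 92321347 to 92328079), rose from 1.64 ± 0.232 to 108 ± 78.9 CPM (SD, n = 3 and 2; log2 fold change 6.03 ± 0.55, adjusted p = 0.00156). It stood at 164 and 52.0 CPM in Tet2-mutant replicates 2 and 3. The interferon-inducible GTPases Tgtp1 and Tgtp2, near-identical neighbours on chromosome 11 whose reads may be shared, rose by 4.92 ± 0.43 and 4.39 ± 0.33 (adjusted p = 0.00148 and 0.000884). Several Gbp genes of this list also resemble each other, and Gbp4, Gbp5, Gbp6 and Gbp7 did not pass while Gbp2, Gbp3, Gbp8 and Gbp9 rose.

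Type I interferon response genes were more divided. Of 32 measured genes 11 rose, 1 fell and 20 did not pass, or 15 and 2 adjusted over the list alone. The median was 1.20 (camera adjusted p = 9.42e-06, and adjusted p = 0.528 with an estimated correlation). Ly6e rose from 614 ± 54.7 to 3749 ± 455 CPM (SD, n = 3 and 2; log2 fold change 2.61 ± 0.25, adjusted p = 0.00195). Zbp1, a sensor of nucleic acids, rose by 2.98 ± 0.31 (adjusted p = 0.00225) and the chemokine gene Cxcl10 by 4.62 ± 0.62 (adjusted p = 0.00631). Cxcl10 was at 111 and 27.7 CPM in Tet2-mutant replicates 2 and 3. Oas3 fell, from 24.3 ± 7.73 to 6.07 ± 0.937 CPM (adjusted p = 0.0361), and its call was absent in each fit without 1 wild-type library. Isg15, a common readout of interferon, did not pass, at 183 CPM in Tet2-mutant replicate 2 and 21.8 CPM in replicate 3 against 22.3 to 38.6 CPM in the wild type. Rises numbered 7, 11 and 10 without wild-type replicates 1, 2 and 3, and 14 and 23 without Tet2-mutant replicates 2 and 3.

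Among inflammatory cytokines and NF-kB targets, 8 of 26 genes rose and 1 fell, or 12 and 2 adjusted over the list alone (median 1.15, camera adjusted p = 0.00129, and adjusted p = 0.28 with an estimated correlation). The call was lost (adjusted p = 0.0543) when only genes at 1 CPM or more in at least 3 libraries were kept. Il18, a cytokine processed by inflammasomes, rose from 5.68 ± 0.397 to 87.3 ± 7.48 CPM (SD, n = 3 and 2; log2 fold change 3.94 ± 0.30, adjusted p = 0.000884), and the adhesion molecule gene Icam1 rose by 2.86 ± 0.27 (adjusted p = 0.00168). Il12b, a subunit of interleukin-12, stood at 0.151 ± 0.0743 CPM in the wild type and at 44.0 and 12.4 CPM in Tet2-mutant replicates 2 and 3 (adjusted p = 0.0032). The cytokines Il1b, Tnf and Il6, examples chosen after their values were seen, did not pass, with log2 fold changes of 0.80, 0.96 and 0.33 (adjusted p = 0.0823, 0.0762 and 0.802). Nfkbiz, an inducible regulator of NF-kB, was the member that fell (log2 fold change -1.06, adjusted p = 0.044), and it passed in none of the fits without 1 wild-type library. The rises were 5, 6 and 5 without wild-type replicates 1, 2 and 3, and 14 and 13 without Tet2-mutant replicates 2 and 3.

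Of the monocyte subset lists, 1 was called. The classical list was not called (camera adjusted p = 0.0819), with 4 of 15 genes risen over all genes and adjusted over the list alone, a median of 0.08 and a mean of 0.56. Its median was -0.27 with upper-quartile scaling, and the list was called higher with no filter (adjusted p = 0.00837) and without Tet2-mutant replicate 3 (adjusted p = 0.0244). Ly86 rose by 3.48 ± 0.27 (adjusted p = 0.000929) and Csf1r, the receptor for macrophage colony-stimulating factor, by 1.82 ± 0.28 (adjusted p = 0.0105). Ly6c2, the surface marker of classical monocytes, did not pass at 420 ± 75.4 against 274 ± 155 CPM (log2 fold change -0.62, adjusted p = 0.263). The non-classical list was called higher, with 8 of 16 genes risen, or 9 adjusted over the list alone. Its median was 1.70 (camera adjusted p = 1.42e-05, and adjusted p = 0.28 with an estimated correlation). Cd300e rose from 5.29 ± 1.31 to 191 ± 78.5 CPM (SD, n = 3 and 2; log2 fold change 5.18 ± 0.39, adjusted p = 0.000884) and Treml4 by 4.20 ± 0.34 (adjusted p = 0.00105). Without wild-type replicate 1, 5 non-classical genes rose.

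Macrophage genes rose in 14 of 19 cases, over all genes and adjusted over the list alone, with a median of 1.70 (camera adjusted p = 3.5e-07, and adjusted p = 0.28 with an estimated correlation). The complement genes C1qa, C1qb and C1qc, side by side on chromosome 4 (136880129 to 136898803), rose by 3.94 ± 0.26, 4.69 ± 0.29 and 4.57 ± 0.30 (adjusted p = 0.000825, 0.000757 and 0.000826). C1qb went from 61.2 ± 6.23 to 1584 ± 443 CPM (SD, n = 3 and 2). Apoe, a lipid carrier made by macrophages, rose from 337 ± 75.6 to 4147 ± 162 CPM (adjusted p = 0.00108). Spic, the transcription factor of red pulp and marrow macrophages, was among the 14. Without wild-type replicates 2 and 3 in turn, 9 macrophage genes rose each time. Conventional dendritic cell genes rose in 8 of 14 cases, or 12 adjusted over the list alone (median 2.13, camera adjusted p = 2.07e-06, and adjusted p = 0.28 with an estimated correlation). Batf3, which the cross-presenting dendritic cell lineage needs, rose from 1.62 ± 0.423 to 87.0 ± 28.0 CPM (log2 fold change 5.75 ± 0.42, adjusted p = 0.000848), and Cd209a by 3.92 ± 0.48 (adjusted p = 0.00456). Dendritic cell rises numbered 4 without wild-type replicate 1 and 12 without Tet2-mutant replicate 2. Plasmacytoid dendritic cell genes were not called as a list (adjusted p = 0.103, 3 of 13 risen, or 4 up and 1 down adjusted over the list alone). Their list median per library was -0.41 in Tet2-mutant replicate 2 and 1.70 in replicate 3. That list was called higher (adjusted p = 0.023) without Tet2-mutant replicate 2.

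T cell transcripts were also higher. B cell genes were divided, with rises mainly in Tet2-mutant replicate 3. T cell and NK cell genes rose in 12 of 24 cases, or 13 up and 1 down adjusted over the list alone. The median was 1.83 (camera adjusted p = 8.65e-06, and adjusted p = 0.398 with an estimated correlation). Cd3g, a chain of the T cell receptor complex, rose from 13.5 ± 3.19 to 218 ± 6.35 CPM (SD, n = 3 and 2; log2 fold change 4.02 ± 0.29, adjusted p = 0.000848). The receptor constant genes Trbc2 and Trac rose by 3.61 ± 0.31 (adjusted p = 0.0013) and 3.95 ± 0.39 (adjusted p = 0.00209). Without wild-type replicate 2, 8 T and NK cell genes rose. In the B cell and plasma cell list 6 of 23 genes rose, or 11 up and 1 down adjusted over the list alone (median 1.76, camera adjusted p = 0.0165, and adjusted p = 0.686 with an estimated correlation). Cd79b, a signalling chain of the B cell receptor, was at 149, 168 and 45.9 CPM in the wild-type libraries and at 363 and 2449 CPM in Tet2-mutant replicates 2 and 3 (log2 fold change 3.54 ± 0.82, adjusted p = 0.0362). The light chain constant gene Iglc2 was at 448 and 4533 CPM in the mutant libraries (log2 fold change 5.44 ± 0.87, adjusted p = 0.0119). Immunoglobulin genes resemble each other and their counts are uncertain. The B cell list was no longer called without wild-type replicate 3 (adjusted p = 0.442) or without Tet2-mutant replicate 3 (adjusted p = 0.118). Of its genes, 0, 5 and 2 rose without wild-type replicates 1, 2 and 3, against 14 and 2 without Tet2-mutant replicates 2 and 3. Cd79b lost its call without wild-type replicate 1 (adjusted p = 0.118), wild-type replicate 3 (adjusted p = 0.052) or Tet2-mutant replicate 3 (adjusted p = 0.0779), and Iglc2 without wild-type replicate 1 (adjusted p = 0.0794).

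Cell cycle lists were called lower, while the number of single genes that passed varied with the test and scaling. In S phase 3 of 25 genes fell, or 5 adjusted over the list alone, and 21 were below every wild-type library in both mutant libraries. The list was called lower (median -1.40, camera adjusted p = 0.000181, and adjusted p = 0.668 with an estimated correlation). Chaf1b, a subunit of the chromatin assembly factor that follows DNA replication, fell from 102 ± 12.7 to 28.6 ± 15.9 CPM (SD, n = 3 and 2; log2 fold change -1.85 ± 0.41, adjusted p = 0.032). The replication genes Gins2 and Pola1 also fell (log2 fold changes -1.49 and -1.76, adjusted p = 0.0325 and 0.0374). In G2 and mitosis 1 of 25 genes fell, Kif20b, over all genes and adjusted over the list alone (log2 fold change -1.96 ± 0.37, adjusted p = 0.0203). Its list median was -1.36 (camera adjusted p = 0.00068, and adjusted p = 0.686 with an estimated correlation). Falls in S phase and in G2 and mitosis numbered 12 and 8 with upper-quartile scaling, 19 and 18 with no filter, 8 and 2 by DESeq2 and 19 and 20 by limma-voom. List medians per library were -0.69 and -2.65 for S phase and -0.59 and -2.90 for G2 and mitosis in Tet2-mutant replicates 2 and 3. Without wild-type replicates 1, 2 and 3 in turn the fitted medians were -1.41, -1.21 and -1.23 for S phase. For G2 and mitosis they were -1.35, -1.26 and -1.20. No gene of either list passed in the fits without 1 wild-type library, 23 and 25 genes fell without Tet2-mutant replicate 2, and 10 and 4 fell without Tet2-mutant replicate 3. In that last fit the G2 and mitosis list was no longer called (adjusted p = 0.0857).

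Neutrophil and erythroid lists were called lower largely through 1 library. In the neutrophil list 2 of 23 genes fell, over all genes and adjusted over the list alone (median -0.88, camera adjusted p = 0.0141, and adjusted p = 0.708 with an estimated correlation). Padi4, an enzyme of neutrophil extracellular trap formation, fell from 334 ± 84.5 to 76.8 ± 53.2 CPM (SD, n = 3 and 2; log2 fold change -2.12 ± 0.49, adjusted p = 0.0362) and Mrgpra2b by 1.51 on the log2 scale (adjusted p = 0.0399). Ngp did not pass at 18912 ± 2776 against 19665 ± 8273 CPM. Padi4 lost its call without wild-type replicate 1 (adjusted p = 0.0957), and Mrgpra2b without any one of the wild-type libraries (adjusted p = 0.156, 0.192 and 0.221). The list median was -0.31 in Tet2-mutant replicate 2 and -2.35 in replicate 3. Without Tet2-mutant replicate 3 the call ended (adjusted p = 0.996, with 1 gene higher and 4 lower), whereas 20 of its genes fell without Tet2-mutant replicate 2. In the erythroid list 1 of 20 genes fell, over all genes and adjusted over the list alone, Epor, the erythropoietin receptor (104 ± 21.4 to 23.6 ± 15.2 CPM, adjusted p = 0.032). The erythroid median was -0.89 (camera adjusted p = 0.0267, and adjusted p = 0.722 with an estimated correlation). Its medians were 0.03 and -3.27 in Tet2-mutant replicates 2 and 3. Without Tet2-mutant replicate 3 the erythroid direction turned (adjusted p = 0.846), without wild-type replicate 3 the call ended (adjusted p = 0.0502). All 20 genes fell without Tet2-mutant replicate 2, and Epor lost its call without wild-type replicates 1, 2 and 3 in turn (adjusted p = 0.0684, 0.0574 and 0.0671). The globin genes of this list are near-identical pairs and uncertain.

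Stromal and endothelial genes were called lower, with 1 of 16 fallen, or 0 adjusted over the list alone (median -2.48, camera adjusted p = 0.00759, and adjusted p = 0.641 with an estimated correlation). Pdgfrb, a receptor of perivascular cells, fell from 1.40 ± 0.441 to 0.107 ± 0.0729 CPM (SD, n = 3 and 2; adjusted p = 0.0466), a level near the floor of 3 counts, which is 0.238 CPM in Tet2-mutant replicate 2 and 0.0554 CPM in replicate 3. It lost its call without each wild-type library (adjusted p = 0.146, 0.139 and 0.133). The list call ended without Tet2-mutant replicate 3 (adjusted p = 0.0706). In the stem and progenitor list, which was not called (adjusted p = 0.0819), 2 genes rose and 2 fell out of 23, or 4 and 7 adjusted over the list alone. Ly6a, the stem cell antigen Sca-1 that interferon also induces, rose from 26.7 ± 13.9 to 1099 ± 695 CPM (log2 fold change 5.36 ± 0.58, adjusted p = 0.00277). Mn1 fell from 0.715 to 1.13 CPM in the wild-type libraries to values under the floor of 3 counts in both mutant libraries (adjusted p = 0.0342), and lost its call without wild-type replicates 1, 2 and 3 in turn (adjusted p = 0.108, 0.0906 and 0.0906). Adgrg1 fell by 2.31 on the log2 scale (adjusted p = 0.0199), a call lost without wild-type replicate 1 (adjusted p = 0.0802). The stem list was called lower without wild-type replicates 1, 2 and 3 in turn (adjusted p = 0.0496, 0.0411 and 0.0279) and without Tet2-mutant replicate 2 (adjusted p = 0.0155), and after subtraction of a wild-type share from that library (adjusted p = 0.045). Without Tet2-mutant replicates 2 and 3 in turn the falls were 16 and 11 for stem and progenitor, 13 and 5 for stromal and 12 and 5 for azurophil genes. The azurophil granule list was likewise not called (adjusted p = 0.0819), with Srgn risen and Hdc, the histamine-forming enzyme, fallen out of 15, or 1 and 3 adjusted over the list alone. Srgn lost its call without wild-type replicates 1, 2 and 3 in turn (adjusted p = 0.0874, 0.0518 and 0.0663). The azurophil list was called lower with upper-quartile scaling (adjusted p = 0.0376), with the filter at 1 CPM in at least 3 libraries (adjusted p = 0.0178), without wild-type replicate 1 (adjusted p = 0.0464) and without Tet2-mutant replicate 2 (adjusted p = 0.00886). Mpo, the granule peroxidase, did not pass at 5119 ± 1136 CPM in the wild type and 1963 and 207 CPM in the mutant libraries (adjusted p = 0.0995).

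Lists of transcription factors, oxidative phosphorylation, ribosomal proteins and the unfolded protein response were called higher, with medians under 1. Of 27 myeloid transcription factors 8 rose, or 12 up and 1 down adjusted over the list alone (median 0.57, camera adjusted p = 0.00121, and adjusted p = 0.487 with an estimated correlation). Batf rose by 3.04 ± 0.28 (adjusted p = 0.0016), Relb, a subunit of the alternative NF-kB pathway, by 3.35 ± 0.34 (adjusted p = 0.00219), and Id2, which dendritic cell development needs, by 2.79 ± 0.28 (adjusted p = 0.00219). Spi1, Cebpa and Irf8 did not pass. Nuclear genes of oxidative phosphorylation rose in 11 of 33 cases, or 14 adjusted over the list alone (median 0.80, camera adjusted p = 4.49e-06, and adjusted p = 0.641 with an estimated correlation). Examples were Ndufs3 (log2 fold change 1.63 ± 0.30, adjusted p = 0.0182) and Sdhb (164 ± 16.9 to 439.5 ± 135 CPM, adjusted p = 0.0209). Ribosomal protein genes rose in 8 of 34 cases, or 16 adjusted over the list alone (median 0.91, camera adjusted p = 3.98e-06, and adjusted p = 0.641 with an estimated correlation), for example Rps19 (log2 fold change 1.41 ± 0.25, adjusted p = 0.0159). Unfolded protein response genes rose in 4 of 22 cases, or 7 adjusted over the list alone (median 0.64, camera adjusted p = 0.00341, and adjusted p = 0.487 with an estimated correlation), led by Herpud1 (log2 fold change 1.56 ± 0.25, adjusted p = 0.0115). Without wild-type replicates 1, 2 and 3 in turn the rises were 3, 5 and 4 for oxidative phosphorylation, 1, 3 and 2 for ribosomal proteins, 2, 3 and 3 for the unfolded protein response and 5, 5 and 6 for transcription factors. Without Tet2-mutant replicates 2 and 3 in turn they were 14 and 19, 14 and 15, 10 and 6, and 12 and 14. With upper-quartile scaling these medians were 0.46, 0.61, 0.38 and 0.37.

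Other lists were not called. Among TET and DNA methylation enzymes 2 of 17 genes rose, over all genes and adjusted over the list alone (camera adjusted p = 0.405). These were the deaminase Apobec1 (log2 fold change 1.92 ± 0.27, adjusted p = 0.00795) and the methyltransferase Dnmt3a (1.43 ± 0.34, adjusted p = 0.0375). Without Tet2-mutant replicates 2 and 3 in turn 7 and 4 genes of this list fell. Dnmt3a lost its call without wild-type replicates 1, 2 and 3 in turn (adjusted p = 0.0828, 0.088 and 0.0876). Immediate early and heat shock genes, which respond to cell handling, were not called (adjusted p = 0.837), with Atf3 and Nr4a1 risen out of 24 and none adjusted over the list alone. With upper-quartile scaling 0 of these genes rose and 4 fell. Atf3 lost its call without each wild-type library (adjusted p = 0.106, 0.0922 and 0.0719), and Nr4a1 without wild-type replicates 2 and 3 (adjusted p = 0.0795 and 0.0827). Glycolysis and hypoxia genes were not called (adjusted p = 0.192), with 4 of 24 risen, or 4 up and 1 down adjusted over the list alone, led by Ankrd37 (log2 fold change 3.88 ± 0.47, adjusted p = 0.0043), with 1 rise left without each wild-type library. Upper-quartile scaling gave 1 rise and 4 falls in that list. The list was called higher without Tet2-mutant replicate 3 (adjusted p = 0.0135) and turned lower without Tet2-mutant replicate 2 (adjusted p = 0.797). Cholesterol synthesis genes were not called (adjusted p = 0.734). Mvd rose out of 22, with none adjusted over the list alone, and lost its call without each wild-type library (adjusted p = 0.0865, 0.0983 and 0.105). Megakaryocyte and platelet genes were not called (adjusted p = 0.74), with Ppbp risen and Gp9 fallen out of 16, or 4 of each adjusted over the list alone. Their fitted median was 0.73 and their mean 0.09, whereas camera gave the lower direction, and the median was -0.85 and -0.59 without Tet2-mutant replicates 2 and 3 in turn. Ppbp lost its call without wild-type replicate 1 (adjusted p = 0.0562), and Gp9 without each wild-type library (adjusted p = 0.122, 0.138 and 0.157). Basophil, mast cell and eosinophil genes were not called (adjusted p = 0.331), with Ccr3, an eosinophil chemokine receptor, risen out of 16, over all genes and adjusted over the list alone. Its call was lost without wild-type replicates 2 and 3 (adjusted p = 0.0679 and 0.069).

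The largest rises were dominated by genes of the exocrine pancreas. Of the 12 genes at the top of the fixed rule, 10 were Cel, Cpb1, Cela2a, Cpa1, Pnlip, Pnliprp1, Gp2, Rnase1, Try4 and Try5. Most of these encode digestive enzymes or other secretory proteins of acinar cells. The other 2 were Htr7 and Cxcl13. Cel, a lipase of pancreatic juice (chromosome 2, 28555795 to 28563403), rose from 0.316 ± 0.0545 to 147 ± 76.7 CPM (SD, n = 3 and 2; log2 fold change 8.86 ± 0.49, adjusted p = 0.000728). It had 19, 28 and 22 counts in wild-type replicates 1, 2 and 3 and 1177 and 10929 counts in Tet2-mutant replicates 2 and 3. Cela2a, an elastase, stood at 114 and 396 CPM and Pnlip, the main pancreatic lipase, at 43.7 and 223 CPM in Tet2-mutant replicates 2 and 3 (log2 fold changes 8.71 ± 0.67 and 8.48 ± 0.77, adjusted p = 0.000884 and 0.00156). Rnase1 rose by 8.70 ± 0.39 (adjusted p = 0.000728), at 92.8 and 84.7 CPM. Gp2 had 5, 3 and 5 counts in the wild-type libraries, at or near the floor of 3 counts, and 326 and 1806 in the mutant libraries. Try4 and Try5 lie side by side on chromosome 6 (41302269 to 41316841) in a family of near-identical trypsinogen genes, so their separate values are uncertain. Cxcl13, a chemokine that draws B cells (chromosome 5, 95956951 to 95961068), rose from 0.564 ± 0.0572 to 239 ± 119.9 CPM (log2 fold change 8.72 ± 0.44, adjusted p = 0.000728). Htr7, a serotonin receptor, was at 93.3 and 4.47 CPM in Tet2-mutant replicates 2 and 3 (log2 fold change 9.37 ± 1.35, adjusted p = 0.00812) and lost its call without wild-type replicate 1 (adjusted p = 0.057).

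**Figure D3:**
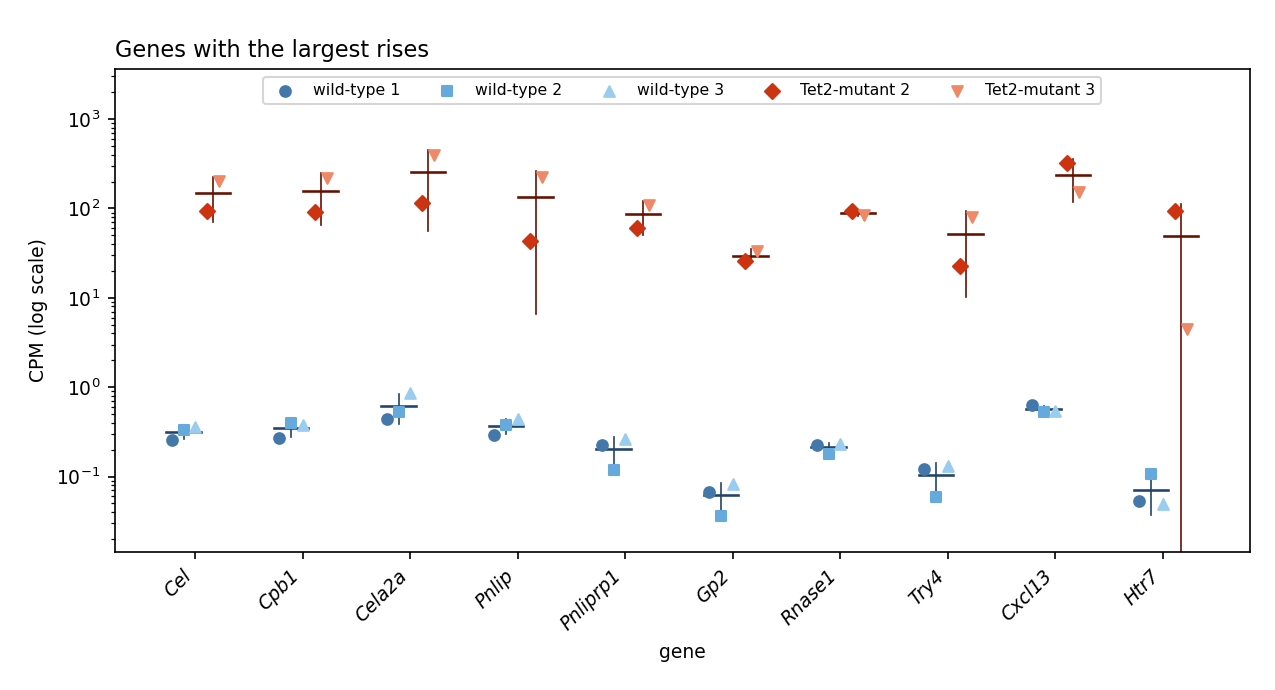
CPM (log axis) of 10 genes with the largest rises in each library, with horizontal lines at the genotype means and vertical lines of 1 SD (n = 3 wild type, n = 2 Tet2 mutant), which run to the axis where the SD exceeds the mean. All wild-type libraries lie under 1 CPM, and Cel stands at 93.2 and 202 CPM in the mutant libraries.

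Among genes with a mean of 10 CPM or more in the higher genotype, the 12 largest falls ran from 5.33-fold to 6.72-fold. Hjurp, the chaperone that loads the centromere histone, fell from 239.6 ± 30.9 to 44.5 ± 32.6 CPM (SD, n = 3 and 2; log2 fold change -2.43 ± 0.50, adjusted p = 0.0262). Chaf1a, the large subunit of chromatin assembly factor, fell from 78.5 ± 4.26 to 13.6 ± 9.11 CPM (log2 fold change -2.54 ± 0.48, adjusted p = 0.0203). Igfbp4, a binding protein of insulin-like growth factors, fell by 2.43 and the helicase Recql4 by 2.48 on the log2 scale (adjusted p = 0.0351 and 0.041). Pidd1, Zcchc3, Fcsk, Pnpla6, Abca13, Eml2, Zxdc and Olr1 made up the rest of the 12, with log2 fold changes between -2.75 and -2.41. Without wild-type replicate 1 none of the 12 passed, with adjusted p = 0.0759 for Hjurp, 0.0661 for Chaf1a, 0.0924 for Igfbp4 and 0.147 for Recql4. The log2 fold changes of these 4 genes in that fit were -2.24, -2.48, -2.39 and -2.35, close to those with all libraries. Without wild-type replicates 2 and 3 Hjurp and Chaf1a kept their calls, while Igfbp4 (adjusted p = 0.0534 and 0.0548), Recql4 (adjusted p = 0.152 and 0.16) and the other 8 lost theirs. Among the 112 named genes past the threshold, 65, 77 and 76 still passed without wild-type replicates 1, 2 and 3, and 112 and 108 without Tet2-mutant replicates 2 and 3.

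Sex-linked transcripts differed between libraries of one genotype. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together stood at 170.4 and 194 CPM in wild-type replicates 1 and 2, at 0.686 CPM in wild-type replicate 3 and at 39.3 and 3.62 CPM in Tet2-mutant replicates 2 and 3. Xist, the transcript of the inactive X chromosome, was at 0.188, 0.179 and 32.3 CPM in wild-type replicates 1, 2 and 3 and at 27.4 and 21.1 CPM in Tet2-mutant replicates 2 and 3. Tet2-mutant replicate 2 thus held both kinds of transcript, with 496 Y-linked and 346 Xist counts. None of the 5 genes passed the genotype test (adjusted p = 0.308 to 0.654). Among the wild-type libraries only replicate 3 was high in Xist. A covariate for high or low Xist therefore sets both mutant libraries against that library alone, so calls lost with it may reflect fewer samples. With it 0 of the 112 named genes and 0 of the lists tested by camera turned direction. With the Xist class of each library (above or below 5 CPM) as a covariate, an alternative chosen after these values were seen, 101 genes passed and all were higher in the mutant. Of these, 14 belonged to the MHC class II list, and 29 of the 112 named genes still passed. In other lists the rises went from 14 to 0 for MHC class I, 11 to 0 for type I interferon, 8 to 0 for inflammatory, 17 to 4 for interferon-gamma, 14 to 5 for macrophage, 8 to 1 for dendritic cell, 12 to 1 for T and NK cell and 8 to 2 for non-classical monocyte genes.

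**Figure D4:**
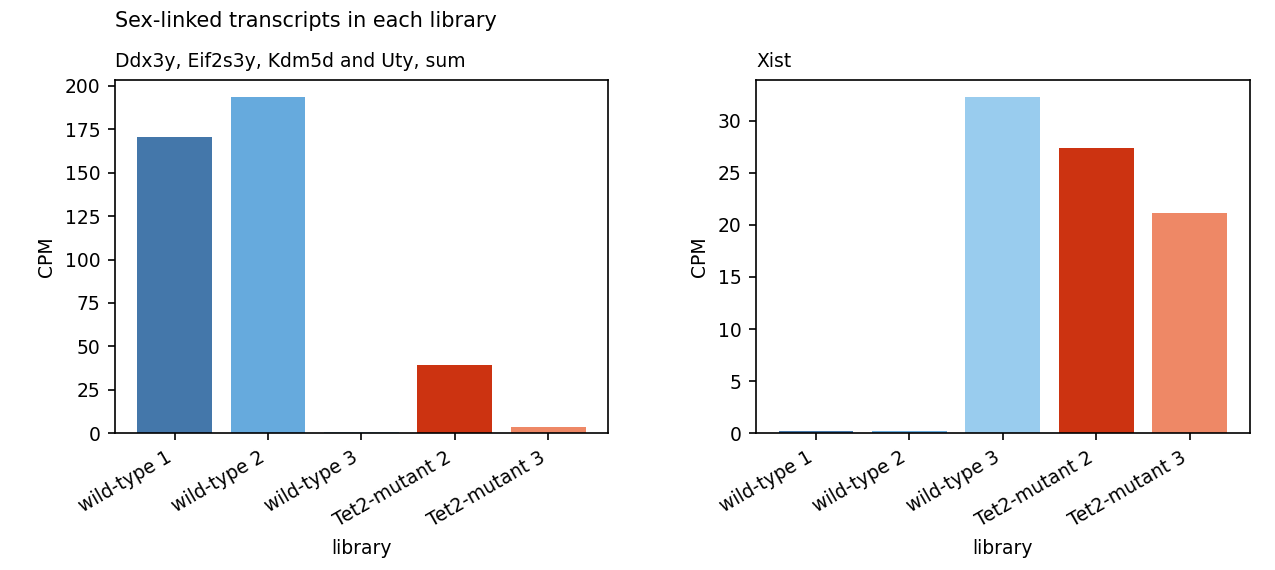
Summed CPM of 4 Y-linked genes (left, linear axis from 0) and CPM of Xist (right, linear axis from 0), 1 bar per library. Tet2-mutant replicate 2 has 39.3 CPM of Y-linked transcripts and 27.4 CPM of Xist.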

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

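The Xist class covariate and the subtraction of a wild-type share from Tet2-mutant replicate 2 were chosen after the data were seen, and every other setting was fixed earlier and run. The covariate leaves replicate 3 as the only wild-type library that is compared with the mutant libraries. Changed genes numbered 4557 with no filter beyond 1 count in total, where more genes were tested, 5109 by the DESeq2 Wald test, 4918 after the subtraction and 101 with the Xist class as a covariate, against 2556. With size factors of DESeq2, upper-quartile scaling, the stricter filter, limma-voom and edgeR robust=TRUE they stayed between 1867 and 3256. Of the 112 named genes past the threshold, 63 kept their call in every leave-one-out fit, 29 in every setting, and 0 reversed. The cause was not tested where none is given.

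Wild-type replicate 1 has no mutant library of the same number, so the replicate block draws the genotype difference from the other libraries only. Calls lost or gained with it are therefore not separable from the smaller number of samples compared. With the replicate block, 984 genes passed and 33 of the 112 named genes were lost. Immediate early and heat shock genes turned higher (adjusted p = 0.747) and the azurophil list was called lower (adjusted p = 0.0483). In that fit 14 S phase, 20 G2 and mitosis and 13 erythroid genes fell. Rises dropped to 0 of 33 for oxidative phosphorylation, 1 of 34 for ribosomal proteins, 9 of 16 for MHC class I, 5 of 27 for transcription factors, 2 of 22 for the unfolded protein response and 1 of 24 for glycolysis and hypoxia, and grew from 6 to 11 of 23 for B cells.

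In the leave-one-out fits the changed genes ranged from 622 without WT replicate 1 to 10862 without Tet2-mutant replicate 2, and the called lists from 16 to 22. Without a mutant library the lone sample left is assumed to vary like the wild-type libraries. The Tet2 log2 fold change ranged from -1.02 to 0.53 in these fits, and was 0.13 to 0.26 without 1 wild-type library. It was 0.00 (0.00486) with size factors of DESeq2, 0.01 (0.00937) by the DESeq2 Wald test and 0.05 (0.0545) by limma-voom.

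Called lists numbered 0 by camera with an estimated correlation and 10 by fry, against 19. Directions turned, with adjusted p ranging over the leave-one-out fits from 3.06e-05 to 0.846 for erythroid genes, 0.573 to 0.996 for immediate early and heat shock genes, 0.0135 to 0.797 for glycolysis and hypoxia and 0.463 to 0.996 for cholesterol synthesis. Of these, erythroid, immediate early and cholesterol genes turned without Tet2-mutant replicate 3, immediate early genes also without WT replicate 3 (0.892), and glycolysis without Tet2-mutant replicate 2. Immediate early genes turned with no filter beyond 1 count in total as well (adjusted p = 0.987). Depth limits Tet2-mutant replicate 2 most, where 3 counts are 0.238 CPM.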

Other observations

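All tests below were chosen after the result was seen, except that on transcript length and GC. H2-Aa, Cd74, Ciita, Cd83, Cxcl9, C1qb and Batf3 rose in the Tet2-mutant libraries. The MHC class II medians per library, 4.09 and 3.54, were close to each other while erythroid medians were far apart, 0.03 and -3.27. The chemokine gene Cxcl13 was at 324 and 154 CPM in Tet2-mutant replicates 2 and 3 and at 0.524 to 0.63 CPM in the wild type.

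The rise of MHC class II genes was set against 3 explanations. Transcript length and GC bias do not account for it, as the list median was 4.01 before and 4.25 after both trends were removed. The Xist class of the libraries does not account for it as the whole cause, as far as 1 wild-type library can show. Wild-type replicate 3, the only wild-type library high in Xist like both mutant libraries, had the lowest list median, -0.39. The medians were 4.09 and 3.54 in Tet2-mutant replicates 2 and 3. With the Xist class as a covariate, which leaves that wild-type library alone in the comparison, the median was 4.63, although the stromal list median moved from -2.48 to -1.45. More macrophages or dendritic cells in the mutant libraries cannot be told apart from an effect within cells, because genotype and composition are confounded, and the smaller of the medians of those lists was 1.70. The Tet2 genotype and the share of B cells stay open.

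Pancreatic enzyme transcripts in both mutant libraries could come from RNA of pancreatic acinar tissue, which stays open. Of 15 acinar genes with 10 or more counts outside the largest rises that prompted the list, 73.3% (11) were at least 4-fold higher in each mutant library than in every wild-type library, under the 75% set for a fit, and 10 of them had 3 counts or more in each mutant library. Among those not raised were 3 genes already at 1 CPM or more in the wild-type mean, so the shortfall does not by itself argue against this source. The filter of 10 counts in total can also be passed through mutant counts alone. Outside the largest rises, 18 acinar genes were under 1 CPM in every wild-type library, with or without a count elsewhere. Of these 18, 10 (55.6%) were raised. Over the 21 raised acinar genes, the ratio of Tet2-mutant replicate 3 to replicate 2 ran from 0.913 to 23.6, with a median of 3.47. The acinar transcripts thus did not stand in the same proportions in both mutant libraries. A general loss of silencing of tissue-specific genes was not seen in both mutant libraries together. The test took 37 genes of islet, liver, muscle, intestine and brain. All had a count in some library and were under 1 CPM in every wild-type library. Of these, 0% were raised in that way (exact binomial 95% upper limit 9.49%, with genes taken as independent). Only 15 of the 37 had a count in a mutant library. Tff1 was at 1.42 CPM in Tet2-mutant replicate 3 and at most 0.016 CPM in the wild type, but had 1 count in replicate 2. A rise in replicate 3 alone could not count, so a loss of silencing there is not excluded. Of 21 genes of these tissues with 10 or more counts, 0 were raised (upper limit 16.1%), or 1 with no floor (upper limit 23.8%). How acinar RNA would have entered bone marrow samples was not tested.

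Y-linked transcripts in Tet2-mutant replicate 2 could reflect a share of wild-type-like material in that library. Its Y-linked sum was 21.6% of the mean of wild-type replicates 1 and 2, and of 58 genes nearly lost in Tet2-mutant replicate 3, 0% lay under 0.5 of that ratio, with a lowest value of 23.8% and a median of 44.0% of the wild type. The 95th percentile was 209%, above what a share of that size alone would give. Only low values could fail this test, so a library that had merely changed less than replicate 3 would pass it too, and it does not decide. Reads crossing evenly between libraries on the sequencer do not account for the Y-linked transcripts, since Tet2-mutant replicate 2 held 2.53 times as many Y-linked counts as replicate 3 (lower 95% limit 2.14, for counting error only) and 496 against 42 in wild-type replicate 3. For a subtraction the share was taken from raw count proportions, without TMM scaling, which gave 13.4% of its counts. The profile subtracted was the mean of all wild-type libraries, including replicate 3 with few Y-linked transcripts, so Y-linked counts were removed only in part. After that subtraction 4918 genes passed and 2 of the 112 named genes lost their call. The sex of the animals is not given in the sources used here.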
